A study of Mus musculus with 87 samples.

How the data were processed

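The series holds 87 samples. They are 36 single oocytes sequenced for poly(A) RNA, 16 for total RNA (a kit that depletes ribosomal RNA instead of selecting tails), and 14 oocytes read by PAIso-seq in 35 runs. Values per gene in the deposited tables are counts per Ensembl gene, 1 table per oocyte, with no normalization. The submitters' processing notes name STAR 2.7.8a, HTSeq 0.11.4 and DESeq2 with GRCm38 and mm10, without saying which step each served, and no annotation release is named. For poly(A) RNA the authors deposited counts per ERCC spike-in RNA (92 species) apart from the gene counts, while the total RNA tables hold both. For PAIso-seq the deposited values are tail length and insert length in nucleotides and the number of passes (other units than counts) per consensus read, plus a mean quality score per read. No upstream tool is stated for those tables. The shortest tails listed are 9 to 14 nt, depending on the run.

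Samples were grouped by genotype and assay from their titles, and by stage where the title names it. Titles of total RNA oocytes name no stage, and these oocytes were grouped as GV. Titles also give each oocyte an f or F number (a plain number in total RNA) shared by 3 to 6 oocytes. The labels do not spell out what this number stands for. Counts of oocytes sharing it were summed and the sum was the replicate, so that p-values measure the spread between these sums. Poly(A) RNA gave 9 sums (GV cKO f3 and f4, GV control f1 and f2, MII cKO f7, f8 and f9, MII control f5 and f6) and total RNA 4 (cKO_1, cKO_2, ctr_1, ctr_2). The sums held 14193997 (f2) to 35498192 (f5) gene counts in poly(A) RNA and 104906501 (ctr_1) to 115548368 (ctr_2) in total RNA. Gene IDs were matched to GENCODE M21 (GRCm38), which holds 55227 of the 55487 IDs. The other 260 carried 0.0062% of poly(A) and 0.0048% of total RNA counts and were kept without a position.

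Differential abundance was tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood F test, two-sided, Benjamini-Hochberg adjusted p under 0.05). The 4 poly(A) groups shared 1 fit with a mean per stage and genotype (5 residual degrees of freedom, common dispersion 0.166). Total RNA was fitted alone (2 residual degrees of freedom, dispersion 0.0866), and the 8 GV sums of both assays together for the interaction of assay and genotype (4, 0.0989). The edgeR fold changes used the default prior count of the fit. A prior count of 2 entered log2 CPM values, such as those behind the changes between f1 and f5 and the slope over all genes. CPM values are TMM-scaled means of the sums with their SD, except for Dis3l2 per oocyte, which are plain CPM. Where a group had no counts, the fold was taken against a floor of 3 counts over the group and written as a lower bound. With 1 to 3 counts, the ratio carries a 95% counting interval. Intervals and floors cover counting error only. TMM, relative size factors (RLE) and DESeq2 scale to the bulk of genes, so changes are relative to the median gene, while ERCC scaling replaces library sizes by ERCC totals. The protocol text read here describes the addition of ERCC RNA for PAIso-seq only, so equal amounts per oocyte in RNA-seq are an assumption.

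Before the data were examined, 20 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. The lists cover 3'-end tailing and decay, deadenylation and decapping, zona and oocyte-secreted genes, maternal effect genes, meiotic cell cycle, spindle and actin, mRNA storage and translation, chromatin and DNA methylation, transcription machinery, two-cell genes, stress and p53, short noncoding RNAs (snRNA, 7SL, 7SK and others), mitochondrially encoded mRNAs, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, proteasome and replication-dependent histones, plus markers of granulosa and cumulus cells, of theca, stroma and endothelium, and of blood and immune cells. Some genes stand in more than 1 list, such as Sohlh1, Ooep, Bcl2l10 and Dnmt3l. With 9 annotation classes this made 29 sets, tested by camera of limma 3.58.1 on voom values with a preset correlation of 0.01 and Benjamini-Hochberg over the sets. Set calls were also computed with an estimated correlation and with fry. The estimated setting also refers the camera statistic to the residual degrees of freedom (5 in poly(A) RNA, 2 in total RNA). Its p-values can therefore rise even where the estimate lies below 0.01. Oxidative phosphorylation in total RNA, with an estimate of 0.00804, went from an unadjusted camera p of 9.06e-11 to 0.0211. A call lost this way does not by itself point to correlation between genes. Named genes are Dis3l2 and, in each comparison, the 8 largest rises and the 8 largest falls that passed with an average of at least 5 CPM and sums that did not overlap between groups, leaving out predicted symbols. Up to 4 members that passed with the smallest adjusted p were added per list (where none passed, up to 2, as values), and 8 genes that passed in 1 direction in both assays at GV.

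The gene to ERCC ratio, PAIso tail length and PAIso insert shares were averaged over oocytes within each f or F number and compared by exact two-sided permutation of those numbers. The smallest p of this test is 0.333 for 2 against 2 and 0.2 for 3 against 2. Runs of 1 PAIso oocyte were pooled first. Pool A (F1, F3 and F4 oocytes) and pool B (F1, F2 and F3) are sets of SMRT cells loaded together. The tables hold no gene and no tail bases, so the share of tails ending in U and tails per gene could not be computed, and ERCC reads could not be set apart. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for these steps.

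Alternatives were RLE scaling, ERCC scaling, no filter on low counts, an average of at least 5 CPM, DESeq2 1.42.0, a log2 fold change of at least 1, a fit on the 2 compared groups, each oocyte as its own sample, limma with the f number as a random block, and leaving out each f number, where a group left with 1 sum was assumed to vary like the others. After the data were examined, 4 oocytes that stood apart (f1_1, f8_38 and f6_32 by correlation with their group, by over 3 median absolute deviations, and f6_30 by depth) were left out of the poly(A) comparisons as a further alternative, and total RNA cKO oocytes 1_2 and 1_3, apart by the same correlation, of the total RNA comparison. ERCC scaling of total RNA, the total RNA ERCC ratio, leaving out sums in the interaction of assays, the gene sets of total RNA with a loess trend in transcript length and GC content removed per sum, the PAIso inserts of 170 to 185 nt without the tail (neighbouring window 200 to 215 nt) and the tails over 150 nt were also added then. Genes drawn from no list and no rule are not named. A result for 1 gene that the rule selects is not reported here. In simulated counts with these depths and dispersions, edgeR recovered 6% of 2-fold and 76% of 4-fold changes at GV (4.7% of calls false), 19% and 83% at MII (7.3%) and 58% and 96% in total RNA (13%). Each run changed 100 genes 2-fold and 100 genes 4-fold, all of at least 5 CPM, among 17007, 16942 and 19417 genes. The data called larger shares (4.64%, 31.5% and 47.2%). The adjusted threshold depends on the share of changed genes, so recovery in the data may be higher. Camera found a planted set and 0 of 28 others in both simulations. Simulated genes were drawn independently, so these runs do not test false set calls from correlation between genes. In the data that correlation was estimated at 0.866 for mitochondrial mRNAs at GV in poly(A) RNA.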

Results

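RNA was measured in single mouse oocytes that were either control (ctr) or conditional knockout (cKO) for Dis3l2, the gene for a 3'-to-5' exoribonuclease that degrades RNA carrying an added U tail. Poly(A) RNA was sequenced from 7 control and 11 cKO oocytes at the germinal vesicle stage (GV, arrested in prophase of meiosis I) and from 8 control and 10 cKO oocytes at metaphase II (MII, the ovulated egg). Total RNA was sequenced from 8 control and 8 cKO oocytes at GV, and poly(A) tails were read by PAIso-seq in 7 control and 7 cKO GV oocytes. Oocytes that share a title number were summed, which gave 2 control and 2 cKO sums at GV, 2 control and 3 cKO sums at MII, and 2 and 2 in total RNA. Gene counts per oocyte ran from 3015706 to 9297342 in GV cKO poly(A) RNA, from 3659113 to 8549195 in GV control, from 3696522 to 10285844 in MII cKO and from 1194861 to 12504987 in MII control. In total RNA they ran from 25063359 to 30542741 in cKO and from 22461193 to 36500303 in control oocytes. The PAIso libraries held 731 to 54283 reads per cKO oocyte and 12755 to 45705 per control oocyte. Reads from mitochondrial genes made up 0.28% ± 0.06 of gene counts in GV cKO poly(A) sums and 0.17% ± 0.02 in GV control sums (SD, n = 2 and 2). They made up 0.73% ± 0.35 in MII cKO and 1.32% ± 0.02 in MII control sums (n = 3 and 2), and 0.86% ± 0.08 against 1.21% ± 0.12 in GV total RNA (n = 2 and 2).

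Dis3l2 (ENSMUSG00000053333, protein-coding, GRCm38 chromosome 1, 86703808 to 87050095) was first followed in every oocyte. Reads over the gene remained in all cKO oocytes, at 4.10 to 14.3 counts per 1000000 (CPM) at GV in poly(A) RNA, 4.63 to 20.3 at MII and 6.89 to 11.0 in total RNA. Control oocytes held 6.43 to 14.8, 8.96 to 56.4 and 14.1 to 18.1 CPM. In total RNA Dis3l2 was lower in cKO, at 8.80 ± 0.24 against 16.3 ± 1.05 CPM (SD, n = 2 and 2), a log2 fold change of -0.89 (SE 0.16, edgeR adjusted p = 0.00776). At MII it stood at 9.04 ± 1.59 against 26.8 ± 14.3 CPM (n = 3 and 2), a log2 fold change of -1.56 (SE 0.38, adjusted p = 0.0121). At GV in poly(A) RNA the values were 6.68 ± 0.51 against 8.53 ± 2.74 CPM (n = 2 and 2), a log2 fold change of -0.35 (SE 0.43, adjusted p = 0.716), which becomes 0.01 without control f2. The call at MII was lost without control f6 (-0.88, adjusted p = 0.151) and with ERCC scaling (-0.45, adjusted p = 0.512). In total RNA the call was lost without cKO_2 (-0.86, adjusted p = 0.0544) and with ERCC scaling (-0.10, adjusted p = 0.661). The counts cover the whole gene, and the labels do not say which exons were deleted.

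**Figure D1:**
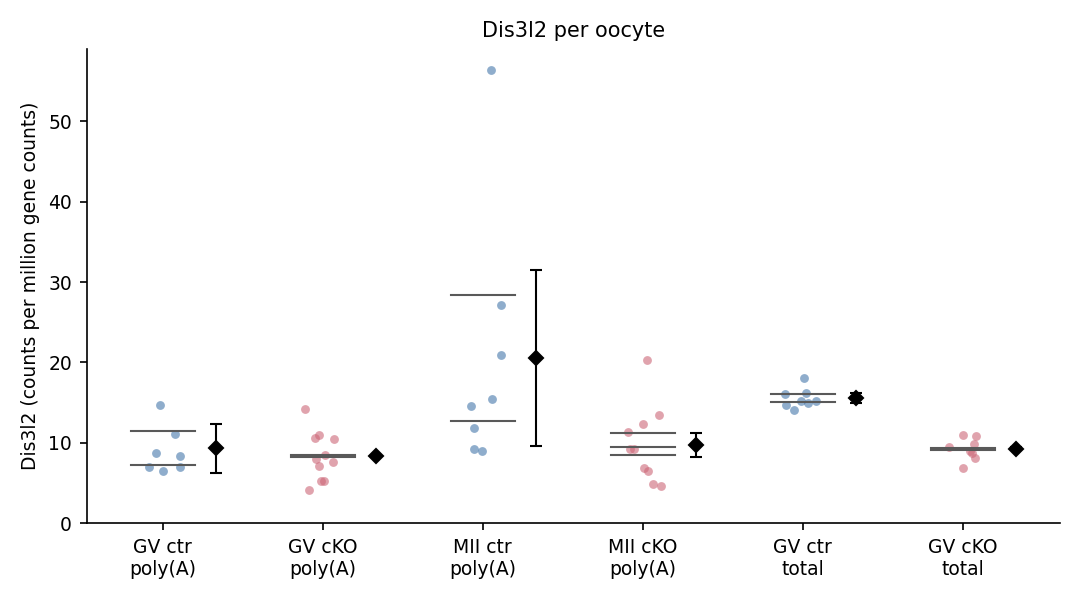
Dis3l2 in counts per 1000000 (y axis) in each oocyte, by group (x axis); each point is 1 oocyte, each grey line the mean of the oocytes sharing a title number, and the diamond with bars the mean ± SD of those means. Total RNA cKO oocytes lie between 6.89 and 11.0 and their controls between 14.1 and 18.1, while 1 MII control oocyte reaches 56.4.

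The first comparison asked which poly(A) RNAs differ between GV oocytes labelled cKO and control. Sohlh1, a germ-cell transcription factor of early follicle growth (chromosome 2, 25842995 to 25847248), rose 58-fold, from 0.647 ± 0.251 to 39.1 ± 5.84 CPM (SD, n = 2 and 2; log2 fold change 5.86, SE 0.51, adjusted p = 0.000971). Itm2a, a membrane protein gene (chromosome X, 107397099 to 107403376), rose 63.2-fold, and the zinc-finger gene Zfp971 61.7-fold. Unc5b, a netrin receptor, rose 40.4-fold to 39.7 ± 0.308 CPM, and Colec12, a scavenger receptor, 45.4-fold. Among the genes that fell, the homeobox gene Lbx1 (chromosome 19, 45232684 to 45235812) went from 18.4 ± 4.87 to 1.14 ± 0.27 CPM (log2 fold change -4.01, SE 0.54, adjusted p = 0.00347). Cd160, a receptor of lymphocytes, dropped 7.14-fold, from 140 ± 1.89 to 19.7 ± 4.64 CPM, the RNA-binding protein gene Rbm47 11.3-fold, and the tight-junction gene Cldn15 9.86-fold. Ptch1, the Hedgehog receptor, was 34.3-fold higher (adjusted p = 0.00873, and 0.0502 without f2). Dlg3 was 33.5-fold higher (adjusted p = 0.00452, and 0.0588 without f1), and Lgr6 7.67-fold lower (adjusted p = 0.00452, and 0.0506 without f3).

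Of 38 replication-dependent histone genes, whose mRNAs normally end in a stem-loop rather than a poly(A) tail, 9 rose, 0 fell and 29 did not pass by edgeR at GV (18 and 3 adjusted over the list alone, 23 and 3 at an unadjusted p under 0.05), and with ERCC scaling 1 passed. Hist4h4 increased 16.1-fold to 40.8 ± 12.2 CPM (adjusted p = 0.00142) and the linker histone gene Hist1h1a 7.38-fold to 120 ± 54.9 CPM (adjusted p = 0.00142). The list median was 2.28 on the log2 scale, or 2.22 with genes that had no counts in 1 group held at their bound (camera adjusted p = 1.55e-08, adjusted p = 0.471 with an estimated correlation and 0.103 by fry), and 1.59 with ERCC scaling. Chromatin regulators split 7 up, 1 down and 47 not passing of 55 (8 and 3 adjusted over the list alone). Kmt2a, which methylates histone H3 lysine 4, rose 28.7-fold to 46.8 ± 7.6 CPM, while the demethylase gene Kdm5a rose 6.27-fold, the DNA dioxygenase gene Tet2 6.2-fold and the deacetylase gene Hdac4 5.17-fold. This list as a whole was not called (adjusted p = 0.982). In the maternal effect list, 1 gene rose, 2 fell and 37 did not pass of 40 (1 and 4 adjusted over the list alone). Its riser was Ago2, the Argonaute slicer, at 196 ± 9.46 against 34.4 ± 7.78 CPM (5.69-fold, adjusted p = 0.00268). The list median was -0.29, or -0.98 with 0 calls with ERCC scaling (camera adjusted p = 0.0307, 0.198 without f1, and adjusted p = 0.471 with an estimated correlation). With ERCC scaling the calls of Hist1h1a (adjusted p = 0.0519), Tet2 (0.065), Kdm5a (0.0698), Hdac4 (0.0829) and Ago2 (0.0838) were lost.

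Meiotic cell cycle genes gave 0 up, 1 down and 56 not passing of 57 at GV (1 and 4 adjusted over the list alone, 4 and 13 at an unadjusted p under 0.05), with a median of -0.28 (camera adjusted p = 0.0153, and adjusted p = 0.471 with an estimated correlation). Spindle and actin genes gave 2 up, 2 down and 44 not passing of 48 (2 and 6 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.00731, and adjusted p = 0.523 with an estimated correlation). ERCC scaling put these 2 medians at -0.97 and -0.99, with 0 calls in either list. The 3'-end tailing and decay list held 1 riser, the uridylyltransferase gene Tut7, and 1 gene that fell, the poly(A) polymerase gene Tent5c, of 45 (2 and 1 adjusted over the list alone). Tut7 was 2.04-fold higher, a call lost without any 1 of f3, f4, f1 and f2 (adjusted p 0.0775 to 0.212). Tent5c went from 1929 ± 160 to 874 ± 14 CPM (adjusted p = 0.00968), a call lost without f3 (0.0711), f4 (0.0788) or f2 (0.0833). Storage and translation genes moved 2 up and 1 down of 42 (2 and 1 adjusted over the list alone). Cpeb2, which binds cytoplasmic polyadenylation elements, rose 15.3-fold from 1.57 ± 0.146 to 24.0 ± 3.15 CPM (adjusted p = 0.000711). Of the stress and p53 list, 4 rose and 1 fell of 38 (5 and 1 adjusted over the list alone), with the p53 target Ccng1 8.93-fold higher at 52.2 ± 0.271 CPM. Among transcription machinery genes 4 rose and 1 fell of 41 (4 and 6 adjusted over the list alone), and Ccnt1, the cyclin of the elongation factor P-TEFb, rose 4.54-fold. Ribosomal protein genes had 0 calls of 78 by edgeR (0 higher and 1 lower at an unadjusted p under 0.05), and nuclear genes of oxidative phosphorylation 0 of 75 (1 and 1). Proteasome genes had 0 of 38 (1 and 2), granulosa markers 0 of 33 (2 and 1) and mitochondrial mRNAs 0 of 7 (3 and 0). By camera with the preset correlation, ribosomal proteins were called as lower without f4 (adjusted p = 0.00056) or f1 (0.00566), and oxidative phosphorylation (0.0016) and the proteasome (0.00334) without f4. Granulosa markers and mitochondrial mRNAs were called as higher without f3 (0.0331 each). With ERCC scaling the calls of Tent5c (0.0788), Tut7 (0.637), Ccng1 (0.0519) and Ccnt1 (0.116) were lost.

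In all, 826 of 17805 tested genes passed at GV (edgeR quasi-likelihood, two-sided, Benjamini-Hochberg 0.05), 603 higher and 223 lower in cKO, on 2 f numbers per genotype. Relative size factors gave 544 higher and 325 lower, DESeq2 1121 and 1003, and ERCC scaling 55 and 60, with the median gene at -0.715 in place of -0.025. The count was 239 without f3, 231 without f4, 202 without f1 and 135 without f2. Other lists at GV had 1 riser of 40 (deadenylation, Zfp36l2), 2 of 32 (zona and oocyte-secreted, Sohlh1 and Sohlh2), 0 of 9 (two-cell genes, 2 higher and 1 lower at an unadjusted p under 0.05), 1 lower of 12 (theca, stroma and endothelium, Pecam1), 1 lower of 6 (blood and immune, Ms4a1) and 1 riser of 6 (short noncoding RNAs, Snord118). Of these genes Sohlh1 kept its call with each f number left out. Zfp36l2 lost it without f1 (0.0873) or f2 (0.0732), Sohlh2 without f3 (0.114), f1 (0.145) or f2 (0.119), and Snord118 without f1 (0.0524). Pecam1 (0.0769 to 0.195) and Ms4a1 (0.101 to 0.186) lost it without any 1 of f3, f4, f1 and f2. With ERCC scaling Zfp36l2 (0.108), Sohlh2 (0.114), Pecam1 (0.0764) and Ms4a1 (0.0714) lost it as well. The short noncoding list was called as higher by camera without f3 (0.0369) or f4 (0.0468).

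Total RNA of GV oocytes, which does not depend on a poly(A) tail, gave the same direction for most of the genes above. Kmt2a rose 119-fold, from 4.19 ± 2.12 to 499 ± 79.3 CPM (SD, n = 2 and 2; log2 fold change 6.89, SE 0.41). Zfp971 rose 123-fold, Unc5b 54-fold, Ptch1 61.4-fold and Colec12 57.5-fold, while Itm2a, with no control counts, was at least 1150-fold higher. Irs2, the insulin receptor substrate gene (chromosome 8, 10984681 to 11008458), rose 348-fold, from 0.103 ± 0.0305 to 36.7 ± 0.104 CPM (log2 fold change 8.44, SE 0.25, adjusted p = 0.000135). The cholesterol exporter gene Abca1 rose 160-fold to 102 ± 20.3 CPM, the transcription factor gene Myb 700-fold and the flippase gene Atp8b2 679-fold. Lbx1 fell 89-fold, from 45.5 ± 1.09 to 0.511 ± 0.232 CPM (SE 0.34, adjusted p = 0.000246), and Shisal1 29.3-fold. Of the genes called in poly(A) RNA, 589 were higher in both (159.5 by chance) and 205 lower in both (55.7), among 16917 tested in both. Across 8946 genes of at least 5 CPM the log2 fold changes correlated with Pearson r = 0.831 and Spearman rho = 0.765, where genes are not independent replicates.

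In total RNA, genes of the protein-making and energy machinery fell relative to the median gene. Of 77 cytosolic ribosomal protein genes, 1 rose, 46 fell and 30 did not pass (1 and 52 adjusted over the list alone), with Rpl4 falling from 224 ± 1 to 101 ± 1.72 CPM. Their median was -1.04 (camera adjusted p = 1.38e-10, and adjusted p = 0.303 with an estimated correlation), or -0.25 with ERCC scaling, where 2 were higher and 18 lower. Nuclear genes of oxidative phosphorylation gave 1 up, 44 down and 30 not passing of 75 (1 and 50 adjusted over the list alone). Among them Cox4i1, a subunit of cytochrome c oxidase, fell 3.43-fold to 14 ± 0.21 CPM. The list median of -0.74 turned to 0.05 with ERCC scaling (camera adjusted p = 1.31e-09, and adjusted p = 0.175 with an estimated correlation). Proteasome genes gave 1 up and 29 down of 37 (2 and 29 adjusted over the list alone), with Psmc1 at 29.3 ± 0.133 against 70.5 ± 1.99 CPM. Their median of -0.75 turned to 0.03 with ERCC scaling (camera adjusted p = 1.32e-08, and adjusted p = 0.175 with an estimated correlation). Fold changes in total RNA rose with transcript length (Spearman rho = 0.35), and these lists have median lengths of 914, 875 and 1591 nt. With a trend in length and GC content removed per sum their medians shrank to -0.51, -0.27 and -0.47 (camera adjusted p = 3.46e-05, 0.00586 and 8.48e-06, and adjusted p = 0.279, 0.299 and 0.299 with an estimated correlation), with 28, 20 and 23 genes lower and 1, 2 and 2 higher.

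Oocyte gene lists also fell relative to the median gene in total RNA. Meiotic cell cycle genes gave 7 up, 38 down and 12 not passing of 57 (7 and 40 adjusted over the list alone), among them Ccnb2, cyclin B2, at 35.0 ± 0.49 against 96.6 ± 3.45 CPM, and Wee2, the oocyte kinase that inhibits CDK1, at 414 against 964. Ccne1, cyclin E1, was among the risers (6.69-fold). The median of -0.52 turned to 0.27 with ERCC scaling (camera adjusted p = 3.01e-06, and adjusted p = 0.175 with an estimated correlation). Maternal effect genes gave 6 up and 27 down of 40 (7 and 28 adjusted over the list alone), with Zfp57, a guardian of imprints, falling from 2080 ± 73.3 to 927 ± 39 CPM and Ago2 rising 11.1-fold. Their median of -0.6 turned to 0.19 with ERCC scaling (camera adjusted p = 1.8e-05, and adjusted p = 0.318 with an estimated correlation). Spindle and actin genes gave 5 up and 31 down of 47 (6 and 31 adjusted over the list alone), with a median of -0.56 that turned to 0.23 with ERCC scaling (camera adjusted p = 1.8e-05, and adjusted p = 0.317 with an estimated correlation). Zona and oocyte-secreted genes gave 6 up and 22 down of 32 (6 and 22 adjusted over the list alone), with Oosp3 at 158 against 427 CPM. Their median of -0.61 turned to 0.18 with ERCC scaling (camera adjusted p = 0.000117, and adjusted p = 0.237 with an estimated correlation).

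Among RNA-regulating genes in total RNA, the tailing and decay list gave 7 up and 19 down of 45 (7 and 20 adjusted over the list alone), with Tut7 2.31-fold higher and Tent5c at 675 ± 0.499 against 1502 ± 80.3 CPM. Its median of -0.32 turned to 0.47 with ERCC scaling (camera adjusted p = 0.0183, and adjusted p = 0.303 with an estimated correlation). Storage and translation genes gave 11 up and 22 down of 42 (12 and 24 adjusted over the list alone), with Cpeb2 16.2-fold higher and Ybx2, an mRNA-packaging protein gene, falling from 180 ± 18.3 to 68.3 ± 4.62 CPM. That median of -0.4 turned to 0.39 with ERCC scaling (camera adjusted p = 0.0169, and adjusted p = 0.341 with an estimated correlation). The lists not called were deadenylation (13 up, 14 down of 40), chromatin (19 and 21 of 55), transcription machinery (14 and 20 of 41), stress and p53 (15 and 9 of 38), two-cell genes (3 and 4 of 16), short noncoding RNAs (3 and 4 of 19), mitochondrial mRNAs (0 and 4 of 7, or 1 and 4 adjusted over the list alone) and histones (20 and 6 of 55, camera adjusted p = 0.111). Left out in turn, cKO_2 (0.0136) or ctr_2 (0.0336) gave a call of histones as higher, and cKO_1 (0.0318) or ctr_2 (0.0336) of mitochondrial mRNAs as lower. Splits with ERCC scaling were 29 and 0 (deadenylation), 38 and 1 (chromatin), 21 and 3 (transcription machinery), 23 and 0 (stress and p53), 6 and 0 (two-cell genes), 4 and 1 (short noncoding RNAs), 28 and 1 (histones) and 3 and 0 (mitochondrial mRNAs, whose median of -0.37 turned to 0.42). With the length and GC trend removed chromatin genes were called as lower (median -0.33, camera adjusted p = 0.00586) and histones as higher (1.34, 0.00065), with adjusted p = 0.279 and 0.545 with an estimated correlation. Of the stress list, Xbp1, a factor of the unfolded protein response, rose 48.8-fold to 26.6 ± 5.12 CPM and Ccng1 14.4-fold to 84.6 ± 15.9. The minor-spliceosome RNA Rnu12 rose 82.7-fold. Markers of other cell types went both ways. Granulosa markers gave 4 up and 3 down of 26, with Ptgs2 24.7-fold and Kitl 6.58-fold higher and aromatase Cyp19a1 at 7.59 ± 1.03 against 21.7 ± 5.38 CPM. Theca, stroma and endothelium markers gave 1 and 1 of 13, and blood and immune markers 0 and 2 of 8 (1 and 3 at an unadjusted p under 0.05). These marker splits were 9 and 1, 3 and 1, and 1 and 0 with ERCC scaling.

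By annotation class, genes labelled TEC (unverified single-exon transcripts) gave 147 up and 25 down of 510 in total RNA (133 and 20 adjusted over the class alone; camera adjusted p = 0.00581, 0.0678 without cKO_1, and adjusted p = 0.175 with an estimated correlation). Small nucleolar RNAs gave 2 up and 4 down of 71 (1 and 0 adjusted over the class alone), with a median of -0.67 that turned to 0.1 with ERCC scaling, where 2 were higher and 0 lower (camera adjusted p = 0.0115, 0.0706 without ctr_1, and adjusted p = 0.544 with an estimated correlation). The misc_RNA class gave 0 up and 7 down of 23, with a median of -0.98, or -0.19 with 2 higher and 0 lower with ERCC scaling (camera adjusted p = 0.0418, and adjusted p = 0.317 with an estimated correlation). That call was lost without cKO_1 (0.0682), cKO_2 (0.0879) or ctr_1 (0.183). With the length and GC trend removed the camera calls of both small nucleolar RNAs (median 0.25, adjusted p = 0.576) and misc_RNA (-0.06, 0.954) were lost. The classes snRNA (0.00586), antisense (0.0177) and protein-coding (0.00582) gained one, with adjusted p = 0.31, 0.17 and 0.075 with an estimated correlation. The classes not called were protein-coding (4069 up, 3853 down of 14960), lincRNA (285 and 195 of 1360), antisense (197 and 112 of 1036), processed pseudogenes (191 and 83 of 1183), snRNA (5 and 1 of 15) and miRNA (1 and 3 of 24).

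In all, 9512 of 20154 genes passed in total RNA (edgeR quasi-likelihood, two-sided), 5123 higher and 4389 lower in cKO, of which 5937 differed at least 2-fold. With ERCC scaling 9654 were higher and 848 lower, and the median gene moved from 0.049 to 0.835. The count was 6073 without cKO_1 and 5797 without cKO_2.

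Whether the genotype difference at GV itself differed between total and poly(A) RNA was tested as an interaction, and 60 of 21428 genes passed (41 with a higher log2 fold change in total RNA, 19 lower). The assays were run on different oocytes, so this test cannot tell the assay apart from the set of oocytes. Mt1, a metallothionein gene (chromosome 8, 94179082 to 94180327), held 35.4 ± 4.38 CPM in cKO against 0.918 ± 0.531 in control in total RNA, and 212 ± 31.9 against 229 ± 4.2 in poly(A) RNA (SD, n = 2 and 2 each). Its difference was 5.27 on the log2 scale (SE 0.44, adjusted p = 0.00606). Abca1 differed by 5.32 (adjusted p = 0.0254), with poly(A) values of 3.35 ± 0.17 against 0.827 ± 0.505 CPM, a call lost without f1 (0.0743), cKO_1 (0.0778), cKO_2 (0.0741) or ctr_1 (0.0519). In the other direction, Scd3, a fatty acid desaturase gene, stood at 0.542 against 6.77 CPM in total RNA and at 7.72 against 6.31 in poly(A) RNA. Its difference of -4.02 (adjusted p = 0.0254) was lost without f2 (0.0518), cKO_1 (0.078), cKO_2 (0.111) or ctr_1 (0.0601). Histone gene Hist4h4 differed by -3.58 (adjusted p = 0.0254), with 63.4 ± 3.61 against 43.0 ± 6.78 CPM in total RNA, and its call was lost without cKO_1 (0.109), cKO_2 (0.141), ctr_1 (0.0601) or ctr_2 (0.0593). The number of calls was 35 without f4, 94 without f1, 21 without f2, 4 without cKO_1, 3 without cKO_2, 7 without ctr_1 and 19 without ctr_2.

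At MII, genes raised in cKO included Zp2 and Zp1 of the egg coat, although the zona list as a whole was not called (median -0.14, camera adjusted p = 0.608). Zp2, a glycoprotein of the zona pellucida (chromosome 7, 120126772 to 120145291), rose 10.7-fold, from 225 ± 11.2 to 2404 ± 754 CPM (SD, n = 2 and 3; log2 fold change 3.42, SE 0.38, adjusted p = 0.000308), and Zp1 rose 5.16-fold. Khdc3 and Ooep, both of the subcortical maternal complex, rose 17.3-fold to 473 ± 353 CPM and 5.83-fold to 1454 ± 797 CPM. Uqcr11, a subunit of respiratory complex III (chromosome 10, 80402997 to 80406830), rose 44.6-fold, from 2.78 ± 1.44 CPM (log2 fold change 5.48, SE 0.43, adjusted p = 8.27e-05). Sohlh1, Selenos and Tmem129, with no control counts at MII, were at least 344-fold, 312-fold and 191-fold higher, and Itm2a had a count ratio of 3370 (95% counting interval 604 to 133000). Lbx1 fell 82.3-fold, from 30.0 ± 1.91 to 0.35 ± 0.239 CPM (log2 fold change -6.36, SE 0.52, adjusted p = 9.79e-05). The sorting receptor gene Sorcs2 fell 13.6-fold, Cmtm8 18.5-fold and Tcl1b5, of an oocyte-expressed cluster, 9.74-fold to 24.1 ± 10.2 CPM.

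Nuclear genes of oxidative phosphorylation gave 49 up, 5 down and 21 not passing of 75 at MII (53 and 7 adjusted over the list alone). Ndufa7 and Ndufa1 of complex I rose 47-fold and 10.3-fold, and Atp5mpl, of the ATP synthase, 9.2-fold to 220 ± 14.7 CPM (adjusted p = 4.45e-05). The list median was 2.07, or 2 at the bound and 3.3 with ERCC scaling, where 61 were higher and 0 lower (camera adjusted p = 1.46e-08, and adjusted p = 0.897 with an estimated correlation). Mitochondrially encoded mRNAs went down instead, with 0 up, 4 down and 3 not passing of 7 by edgeR (0 and 7 adjusted over the list alone, 0 and 7 at an unadjusted p under 0.05). Among them mt-Co1, a cytochrome c oxidase subunit, stood at 673 ± 205 against 1693 ± 14.2 CPM (log2 fold change -1.33, adjusted p = 0.00403; -0.34 with ERCC scaling, adjusted p = 0.5). Without f6 the calls of mt-Nd5, mt-Nd2 and mt-Nd4 were lost (adjusted p = 0.051, 0.0603 and 0.075), as they were with ERCC scaling (0.169, 0.126 and 0.137). The list median was -1.56 (camera adjusted p = 0.00118, and adjusted p = 0.897 with an estimated correlation), or -0.67 with ERCC scaling. Ribosomal protein genes gave 26 up, 3 down and 49 not passing of 78 (26 and 3 adjusted over the list alone), with Rpl41 11.3-fold higher at 108 ± 27.1 CPM. Their median was 1.02, or 0.98 at the bound and 2.22 with ERCC scaling, where 45 were higher and 0 lower (camera adjusted p = 0.0486, 0.292 without f7, 0.0899 without f5, and adjusted p = 0.897 with an estimated correlation). Histones gave 25 up, 0 down and 13 not passing of 38 (26 and 0 adjusted over the list alone, 28 and 0 at an unadjusted p under 0.05), with Hist4h4 20.4-fold higher at 35.0 ± 5.86 CPM and Hist1h4a 29.2-fold. Their median was 3.11, or 2.59 at the bound and 4.22 with ERCC scaling (camera adjusted p = 1.47e-05, and adjusted p = 0.897 with an estimated correlation).

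Meiotic cell cycle genes gave 5 up, 23 down and 29 not passing of 57 at MII (6 and 24 adjusted over the list alone). Wee2 fell from 913 ± 98.4 to 373 ± 50.3 CPM and Ccnb2 from 273 ± 13.3 to 115 ± 18.8, while Ensa, an inhibitor of the phosphatase that reverses mitotic phosphorylation, rose 4.76-fold and the ubiquitin-conjugating enzyme gene Ube2c 3.91-fold. The list median of -0.37 turned to 0.72 with ERCC scaling (camera adjusted p = 0.00418, and adjusted p = 0.897 with an estimated correlation). Spindle and actin genes gave 7 up and 16 down of 48 (7 and 16 adjusted over the list alone), with Tubb2a 4.69-fold higher and Ckap5 at 177 ± 18.8 against 423 ± 53.4 CPM. Their median of -0.25 turned to 0.84 with ERCC scaling (camera adjusted p = 0.0426, and adjusted p = 0.897 with an estimated correlation). That call was lost without f8 (0.0654), f9 (0.112) or f5 (0.219). ERCC scaling ended the calls of Wee2 (-0.23, adjusted p = 0.644), Ccnb2 (-0.1, 0.883) and Ckap5 (-0.18, 0.738).

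Lists not called at MII held single genes with large changes. In storage and translation (9 up, 11 down of 42), Lsm14b, a protein of oocyte mRNA granules, fell from 3284 ± 553 to 833 ± 107 CPM (log2 fold change -1.98, -0.9 with ERCC scaling). In the maternal effect list (10 and 12 of 40), Ago2 rose 13.8-fold to 305 ± 43 CPM and Nlrp4b fell from 658 ± 25.2 to 197 ± 64.4. Of the chromatin list (10 and 12 of 55), Kdm5a rose 26.7-fold to 120 ± 13.1 CPM, Kmt2a 46.7-fold and Tet2 8.13-fold. The deadenylation list (4 and 10 of 40, or 6 and 11 adjusted over the list alone) held Cnot7, a CCR4-NOT deadenylase, at 1142 ± 80.1 against 2541 ± 282 CPM (log2 fold change -1.15, -0.08 with ERCC scaling). The tailing and decay list gave 7 and 8 of 45, zona and oocyte-secreted genes 12 and 10 of 32, transcription machinery 10 and 8 of 41, the proteasome 7 and 6 of 38, stress and p53 7 and 7 of 38, two-cell genes 1 and 0 of 9, and short noncoding RNAs 2 and 0 of 6. Granulosa markers gave 8 up and 3 down of 33, with a median of 1.57, or 0.65 at the bound. Kitl rose 2.97-fold to 36.3 ± 5.1 CPM and Ptgs2 17.8-fold, and Esr2 was at 58.5 against 130 CPM, a call lost without f6 (0.0795). Theca, stroma and endothelium markers gave 0 and 1 of 12 (2 and 1 at an unadjusted p under 0.05), the gene being Pecam1, and blood and immune markers 1 and 2 of 6. With ERCC scaling the calls of Lsm14b (adjusted p = 0.0934), Cnot7 (0.892), Nlrp4b (-0.73, 0.131), Esr2 (-0.03, 0.961) and Pecam1 (-0.48, 0.351) were lost. The list splits became 18 and 0 (storage and translation), 17 and 0 (maternal effect), 16 and 0 (chromatin), 19 and 0 (deadenylation), 21 and 0 (tailing and decay), 13 and 1 (zona), 16 and 0 (transcription machinery), 16 and 1 (proteasome), 14 and 0 (stress and p53), 2 and 0 (two-cell genes) and 3 and 0 (short noncoding RNAs). Those of the granulosa, theca and blood markers became 16 and 0, 4 and 0, and 1 and 0.

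In all, 5608 of 17805 genes passed at MII, 3253 higher and 2355 lower in cKO (edgeR quasi-likelihood, two-sided). With ERCC scaling 6442 were higher and 139 lower, and the median gene moved from 0.172 to 1.247. The count was 3358 without f6. Genes called at GV in poly(A) RNA were called again at MII in 559 cases of higher (110.2 by chance) and 186 of lower (29.5), among 17805.

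**Figure D2:**
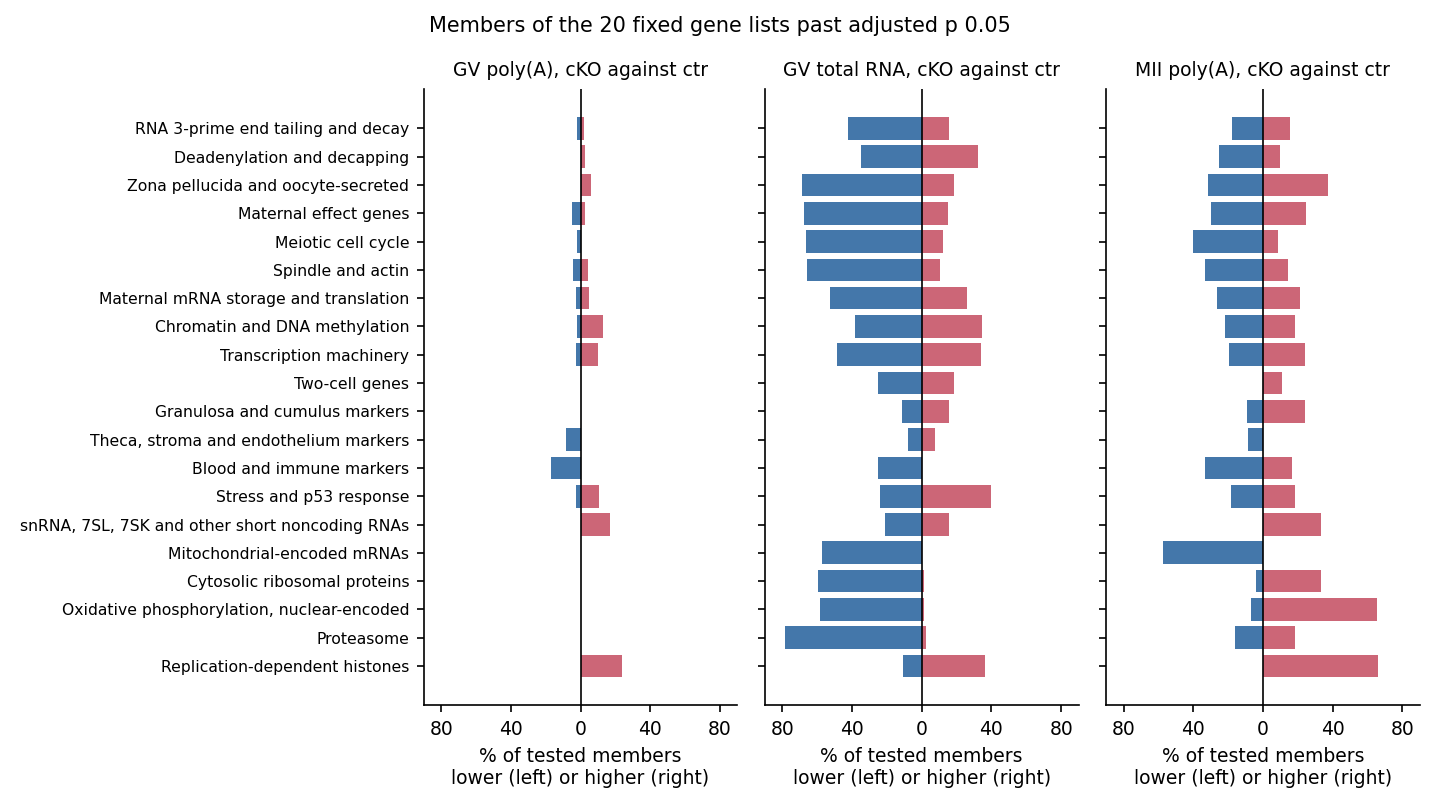
Percent of the tested members of each of the 20 fixed gene lists (y axis) that passed adjusted p 0.05, lower to the left and higher to the right (x axis, percent), in cKO against control for GV poly(A), GV total and MII poly(A) RNA with TMM scaling. Oxidative phosphorylation has 49 members higher and 5 lower of 75 at MII, and 1 higher and 44 lower of 75 in GV total RNA, where the list median is 0.05 with ERCC scaling.

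The change from GV to MII, when transcription is silent and maternal RNA is degraded, was compared within each genotype. In controls Khdc3 fell 93.7-fold, from 2570 ± 588 to 27.4 ± 4.32 CPM (SD, n = 2 and 2; log2 fold change -6.55, SE 0.65, adjusted p = 7.51e-05), against 4.77-fold in cKO, from 2256 to 473. Ribosomal protein genes in controls gave 2 up and 66 down of 78 (2 and 68 adjusted over the list alone), among them Rps3, at 1.59 ± 0.544 against 82.2 CPM. Oxidative phosphorylation gave 2 and 69 of 75 (2 and 70 adjusted over the list alone), among them Ndufa8, which fell 20.2-fold. Their medians were -3.75 (-3.72 at the bound) and -3.66 (camera adjusted p = 3.73e-15 and 8.53e-19, and adjusted p = 0.432 and 0.432 with an estimated correlation). In cKO these lists gave 1 and 51 of 78 (1 and 56 adjusted over the list alone) and 1 and 36 of 75 (1 and 40), with medians of -2.23 and -1.12 (camera adjusted p = 2.87e-17 and 1.52e-10, and adjusted p = 0.446 and 0.529 with an estimated correlation). Proteasome genes gave 4 up and 23 down of 38 in controls (median -1.36, camera adjusted p = 0.00029, and adjusted p = 0.432 with an estimated correlation) and 4 and 20 in cKO (median -1.19, camera adjusted p = 8.51e-06, and adjusted p = 0.392 with an estimated correlation). With ERCC scaling the medians of ribosomal proteins, oxidative phosphorylation and the proteasome were -7.24, -7.15 and -4.83 in controls and -3.78, -2.71 and -2.9 in cKO. Psmb1 fell 20.3-fold in controls and Psma6 7.36-fold in cKO.

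Omt2a and Omt2b, named for oocyte maturation, rose 42.7-fold to 3885 ± 1100 CPM and 38.7-fold to 6177 ± 2260 CPM in controls, and 11.9-fold and 9.43-fold in cKO. The secreted protein gene Oosp3 rose 41.8-fold in controls. The rises of Omt2a, Omt2b and Oosp3 are relative to the median gene, which with ERCC scaling lay at -3.668 in controls and -1.734 in cKO. Their size and their contrast between genotypes therefore depend on the scaling. Mitochondrial mRNAs gave 7 up of 7 in controls (median 4.21, camera adjusted p = 2.03e-06, and adjusted p = 0.432 with an estimated correlation). They gave 6 of 7 in cKO (7 adjusted over the list alone; median 1.77, camera adjusted p = 0.000456, and adjusted p = 0.529 with an estimated correlation). With ERCC scaling the medians were 0.72 and -0.14, and in controls mt-Co1 turned to -0.34. Chromatin genes gave 24 up and 6 down of 55 in controls and 17 and 3 in cKO, with medians of 0.54 and 0.53 that turned to -2.95 and -1.21 with ERCC scaling (camera adjusted p = 0.000762 and 3.39e-05, and adjusted p = 0.274 and 0.133 with an estimated correlation). The kinase gene Cdk1 fell 11.8-fold in controls and 9.55-fold in cKO, to 13.6 ± 3.95 and 15.1 ± 6.06 CPM, and the tubulin gene Tubb4b 7.27-fold and 7.64-fold. Meiotic genes (24 up, 14 down of 57), deadenylation genes (15 and 7 of 40) and histones (0 and 14 of 38) were also called in controls (camera adjusted p = 0.0477 each, and adjusted p = 0.432, 0.437 and 0.818 with an estimated correlation). In cKO the same lists gave 19 and 8, 12 and 4, and 0 and 7 (camera adjusted p = 0.0318, 0.0213 and 0.00046, and adjusted p = 0.446, 0.446 and 0.586 with an estimated correlation), and all 3 medians were negative in both genotypes with ERCC scaling. Zona genes gave 15 up and 12 down of 32 in controls and 12 and 6 in cKO, with medians of 0.75 and 0.53 that turned to -2.67 and -1.14 with ERCC scaling (camera adjusted p = 0.0515 and 0.00555, and adjusted p = 0.584 and 0.446 with an estimated correlation). Granulosa markers gave 3 up and 9 down of 33 in controls and 4 and 8 in cKO. Their Inha, inhibin alpha, had a GV to MII count ratio of 1020 in controls (95% counting interval 182 to 40300). The cell cycle gene Ccnd2 had a ratio of 1860 (635 to 9010) in controls and fell 229-fold in cKO.

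Between the stages 7084 genes passed in controls, 2969 higher and 4115 lower at MII, and 3711 in cKO, 1595 and 2116 (edgeR quasi-likelihood, two-sided). With ERCC scaling the splits were 8 and 15348, and 20 and 10696, with the median gene at -3.668 in place of -0.226 and at -1.734 in place of -0.058. DESeq2 gave 2706 and 2246 in cKO. The cKO count was 1873 without f3 and 1471 without f4. Genes rising in both genotypes numbered 1434 (266 by chance) and falling in both 1812 (489). Across 9847 genes of at least 5 CPM the log2 changes correlated with Pearson r = 0.838 and Spearman rho = 0.861. Of genes chosen as falling at least 4-fold between f1 and f5 (1538 genes), the median change in the other pair of control sums was -3.09, against -1.71 in cKO (f7 -1.38, f8 -1.84, f9 -1.91). For the 401 genes rising at least 4-fold these medians were 2.38 and 1.37. Changes of both classes are with TMM scaling, and with ERCC scaling only 8 genes were called as rising in controls.

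**Figure D3:**
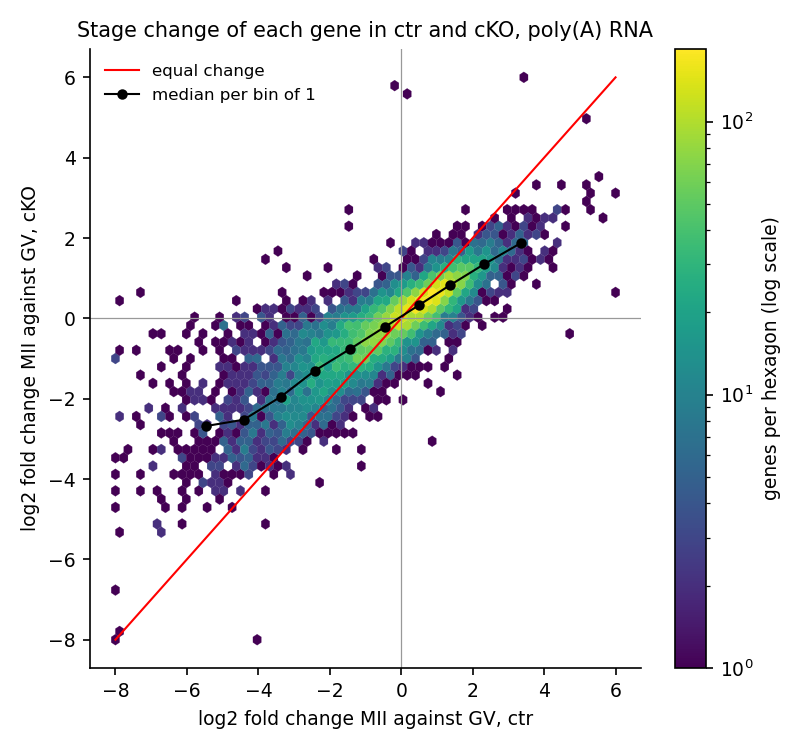
Each hexagon counts genes by their log2 change from GV to MII in control (x axis) and cKO (y axis) poly(A) RNA with TMM scaling. The red line marks equal change and the points the median per bin of 1 log2 unit of the control change. The medians lie closer to 0 than the red line at both ends, and across genes Pearson r is 0.838. Noise in the control change used for the bins pulls the end medians towards 0 even where both genotypes change alike. With ERCC scaling the median gene lies at -3.668 in control and -1.734 in cKO.

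The stage by genotype interaction tested this difference directly, and 267 of 17805 genes passed, 254 with a higher and 13 with a lower genotype log2 fold change at MII than at GV (edgeR, two-sided). Uqcr11 stood at 122 ± 35.4 against 147 ± 16.2 CPM at GV, and its difference was 5.75 on the log2 scale (SE 0.54, adjusted p = 0.00245). Ndufa7 differed by 5.75 (adjusted p = 0.00291), Atp5mpl by 3.13 (adjusted p = 0.00234) and Rpl41 by 3.98 (adjusted p = 0.00353). Zp2, at 2870 ± 38.3 against 2258 ± 1180 CPM at GV, differed by 3.07 (SE 0.50, adjusted p = 0.0189), a call lost without f3 (0.103), f4 (0.062) or f6 (0.0543). Khdc3 differed by 4.30 (SE 0.73, adjusted p = 0.023), lost without f3 (0.134), f4 (0.0611), f1 (0.0508), f2 (0.0911) or f6 (0.0654). Lower at MII relative to GV was mt-Co1, by -2.10 (SE 0.39, adjusted p = 0.0294), lost without f3 (0.0802), f4 (0.0982), f1 (0.117), f2 (0.0979) or f6 (0.0625), and with ERCC scaling (-0.4, adjusted p = 0.562). Lsm14b differed by -1.48 (0.3 with ERCC scaling), lost without f3 (0.108), f4 (0.0853), f1 (0.0957), f2 (0.0939), f8 (0.0536) or f5 (0.0559). Oxidative phosphorylation gave 22 up and 0 down of 75 (45 and 2 adjusted over the list alone; camera adjusted p = 1.91e-20, and adjusted p = 0.671 with an estimated correlation; 67 and 0 with ERCC scaling). Ribosomal protein genes gave 7 and 0 of 78 (20 and 1 adjusted over the list alone; camera adjusted p = 5.74e-06, and adjusted p = 0.879 with an estimated correlation; 51 and 0 with ERCC scaling). The mitochondrial mRNAs gave 0 and 1 of 7 (0 and 7 adjusted over the list alone; camera adjusted p = 7.52e-08, and adjusted p = 0.671 with an estimated correlation), with a median of -2.48, or -0.9 and 0 calls with ERCC scaling. The number of calls was 23 without f3, 88 without f4, 102 without f1, 71 without f2 and 140 without f6, and DESeq2 gave 920 higher and 232 lower. ERCC scaling gave 6000 higher and 5 lower, and 678 genes passed without the 4 oocytes that stood apart. For Dis3l2 itself the interaction was -1.21 (adjusted p = 0.33), which turned to 0.63 with ERCC scaling (adjusted p = 0.507).

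ERCC spike-in RNA gave a relative measure of RNA per oocyte, if equal amounts were added. At GV the log2 ratio of gene counts to ERCC counts in poly(A) RNA was 7.67 ± 0.12 in cKO and 8.54 ± 0.21 in control sums (SD, n = 2 and 2), a difference of -0.86 (exact two-sided permutation p = 0.33, the smallest that 2 against 2 can give). In total RNA of GV oocytes it went the other way, 9.75 ± 0.04 against 9.17 ± 0.03, a difference of 0.59 (exact permutation p = 0.33). These SDs are those of 2 means each. Single control oocytes ran from 8.4 to 9.89 and overlapped cKO oocytes, at 9.43 to 10.02. Total RNA oocytes had counts for 40 to 52 of the 92 ERCC species, against 88 to 92 in poly(A) RNA. The difference between these assays was not tested. At MII the poly(A) ratio was 6.24 ± 0.57 in cKO and 5.57 ± 0.14 in control (n = 3 and 2), a difference of 0.67 (exact permutation p = 0.2, the smallest that 3 against 2 can give), or 0.38 without f7. From summed counts the MII difference was 0.59 (exact permutation p = 0.4). From GV to MII the ratio fell 7.8-fold in controls (-2.96, exact permutation p = 0.33) and 2.7-fold in cKO (-1.43, exact permutation p = 0.2), each p the smallest possible. The genotype difference changed by 1.53 between GV and MII (exact two-sided permutation p = 0.0333 over 60 arrangements of the genotype labels within stage). The null of this permutation is no genotype difference at either stage. It therefore cannot tell a changed difference from an equal difference at both stages.

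**Figure D4:**
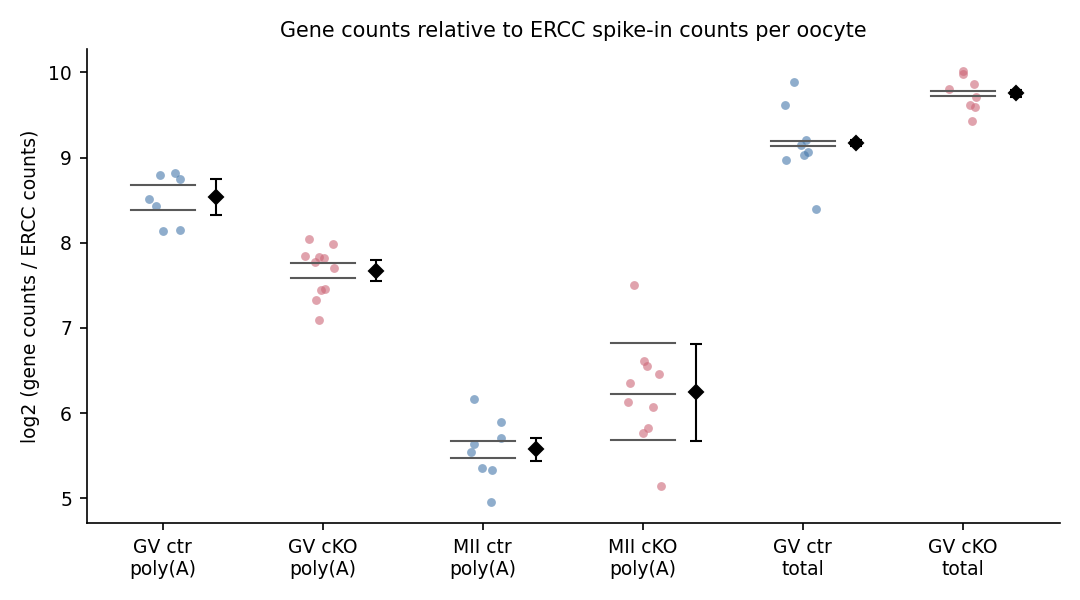
Log2 ratio of gene to ERCC counts (y axis) in each oocyte by group (x axis); points are oocytes, grey lines the means of oocytes sharing a title number, and diamonds with bars the mean ± SD of those means. Controls go from 8.54 at GV to 5.57 at MII and cKO oocytes from 7.67 to 6.24. In GV total RNA the cKO mean lies above the control mean, 9.75 against 9.17, with single oocytes that overlap.

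Poly(A) tails of GV oocytes, read by PAIso-seq, which sequences whole tailed molecules on a long-read platform, had a median of 63.75 ± 3.18 nt in cKO and 66.75 ± 14.5 nt in control (SD of the F-number means, n = 2 and 2). The difference of -3.0 nt was within the spread (exact two-sided permutation p = 1.0, where 0.33 is the smallest). By F number the means of oocyte medians were 61.5 and 66.0 nt in cKO (F1, F2) and 56.5 and 77.0 nt in control (F3, F4). The direction turned without F4 (7.25 nt) and was -13.25 without F3. It was -4.5 in library pool A and 6.33 in pool B. Tails over 150 nt made up 15.05% ± 2.82 of reads in cKO and 12.05% ± 4.95 in control (exact permutation p = 0.667), and this difference of 3.0 points turned to -0.5 without F3. The read tables carry no gene assignment or tail bases, so tails per gene and terminal U were not analysed here.

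**Figure D5:**
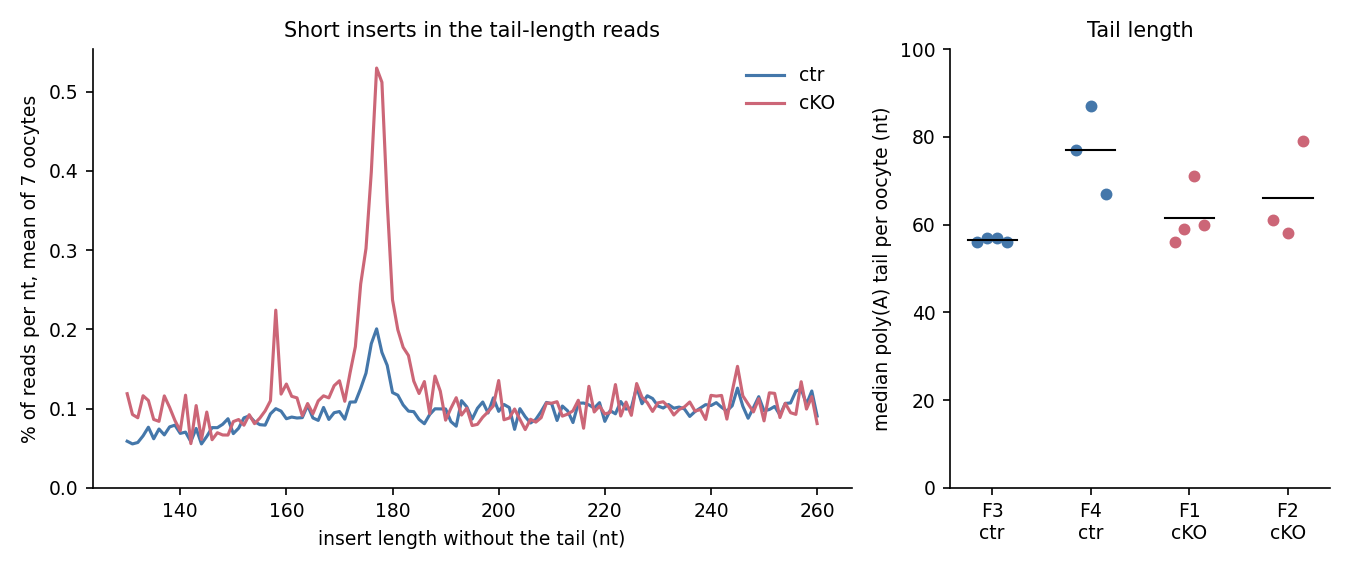
Left, percent of PAIso reads (y axis) at each length of the insert without its tail (x axis, nt), mean over the 7 oocytes of each genotype; right, median tail length (y axis, nt) of each oocyte by F number (points), with lines at the F-number means. At 177 nt cKO oocytes hold 0.5297% of reads and control oocytes 0.2006%; the F-number mean tails are 61.5 and 66.0 nt in cKO and 56.5 and 77.0 nt in control.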

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

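Tests chosen only after the result was seen are the retention test, the slope over genes not chosen by their call, the ratios from fits on 2 groups with the demand that both kinds of fit exceed a ratio of 3, and all tests on PAIso inserts.

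The genotype difference differed between the stages for 267 genes and between total and poly(A) RNA for 60 genes, each by an interaction test in edgeR. These counts were 23 without f3, 88 without f4, 102 without f1, 71 without f2 and 140 without f6 for the stages, and 35 without f4, 94 without f1, 21 without f2, 4 without cKO_1, 3 without cKO_2, 7 without ctr_1 and 19 without ctr_2 for the assays. The poly(A) gene to ERCC ratio changed its genotype difference by 1.53 (log2) from GV to MII (exact two-sided permutation p = 0.0333, whose null is no genotype difference at either stage). Dis3l2 stood at 56.37 CPM in MII control oocyte f6_32, far above the other 7 of its group. Mitochondrial genes made up 0.114% of counts in GV control oocyte f2_8, below the other 6. Of 31 groups of values examined for such gaps 2 were that far apart, where chance gives 1.6, about 1 in 20. Reads outside annotated features, which no comparison used, were more frequent in every cKO sum than in every control sum, at 11.25% ± 1.15 against 9.53% ± 1.05 at GV in poly(A) RNA, 9.24% ± 0.77 against 7.78% ± 0.04 at MII and 25.21% ± 0.13 against 21.86% ± 0.2 in total RNA.

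More genes differed between genotypes at MII (5608, or 3358 without f6) than at GV (826, or 239 without f3, 231 without f4, 202 without f1 and 135 without f2) in poly(A) RNA. With every sum thinned to 14193997 counts the MII count was still 5.75 times the GV count (5.51 to 6.01 over 5 draws). Fits on the 2 compared groups gave 3.12 (2.98 to 3.23), against 3.14 without thinning (4310 and 1373 genes). The excess at MII thus remained at equal depth in both kinds of fit, which argues against depth as the whole cause, although the lowest draw lay below the limit of 3. The additional f number at MII is left open. The smallest MII count with 1 of f7, f8 and f9 left out was 5.32 times the GV count (4397), or 2.18 times with fits on 2 groups (2990, without f7). A candidate explanation is that cKO eggs keep poly(A) RNAs that controls lose during maturation. Genes higher in cKO against f5 overlapped those that fell in controls between GV and f6. This overlap was 2.69 times the number expected by chance (2.39 with f5 and f6 exchanged). That number takes the calls as independent, although f5 and f6 are both MII control sums. Part of the overlap may therefore come from the control level that they share. MII was sequenced for poly(A) RNA only, so loss of RNA and loss of tails cannot be told apart. With TMM scaling retention alone leaves open the converse. Genes lower in cKO that rose in controls were 4.48 times the number expected by chance (3.64 exchanged). Both overlaps are relative to the median gene and were not computed with ERCC scaling. With ERCC scaling 8 genes were called as rising from GV to MII in controls and 15348 as falling. At MII 139 were then lower in cKO and 6442 higher. If equal ERCC amounts were added, few genes were thus called for the converse, which depends on the scaling. That scaling takes 1 ERCC total per sum as exact, although the MII ratio was 5.68 in cKO f8 and 5.67 in control f5. Genes not called as lower are not shown to be absent from the converse.

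Many more genes differed at GV in total RNA (9512, or 6073 without cKO_1 and 5797 without cKO_2) than in poly(A) RNA (826, or 239 without f3, 231 without f4, 202 without f1 and 135 without f2). Thinning total RNA to the depth of the poly(A) sums left 7.89 times as many calls (7.79 to 8), or 4.75 times (4.68 to 4.81) the 1373 of a poly(A) fit that, like that of total RNA, holds 2 groups, which argues against depth as the whole cause. A larger spread between poly(A) sums as the whole cause would leave equal fold changes, but the slope of poly(A) on total RNA log2 fold changes was 0.605 (0.574 to 0.651 with 1 sum left out) over the 5762 genes called in total RNA, and 0.6 to 0.67 (0.568 to 0.714 with 1 poly(A) sum left out) over all 8946 genes of at least 5 CPM, with the other pair of total RNA sums as instrument against noise. Removing a trend in transcript length and GC content per sum kept 85.5% of the total RNA calls, and lowered the rank correlation of fold change with length from 0.35 to 0.03. What stays open is a part for the larger spread (median SE 0.32 in poly(A) and 0.14 in total RNA, with 6% and 58% of simulated 2-fold changes recovered when few genes were changed). A difference between the RNA pools that the kits select stays open too, and either may lower the poly(A) count. The assays were also run on different oocytes under different title numbers, so kit and set of oocytes cannot be told apart.

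PAIso reads with an insert, tail excluded, in the window around the peak at 177 nt made up 3.99% ± 0.31 in cKO and 2.05% ± 0.53 in control (n = 2 and 2 F numbers), with both cKO F numbers above control (exact two-sided permutation p = 0.33, the smallest possible) only if oocyte F2_7 (8.816%) is kept: without it the F2 mean went from 4.21% to 1.91%, below control F4 (2.43%). The ratio was 2.02 in 1 pool of SMRT cells and 2.09 in the other, and 1.41 in pool B without oocyte F2_7, the lowest with 1 oocyte left out, which argues against the pool of SMRT cells. The ratio of 1.95 around the peak compares with 0.96 just above 200 nt and at most 1.27 in 13 other windows as wide. It stayed the highest with each oocyte left out in turn, most narrowly without F2_7 (1.39 against 1.25). This argues against a general excess of short inserts as the whole cause of the mean difference, in a window set on the peak in these data. The share was largest in F2_7 and F1_7 (6.055%), which were not left out together. The other cKO oocytes, at 1.778% to 3.891%, overlapped control oocytes, at 1.149% to 3.315%, so for them a general excess stays open. The reads carry no gene in the tables used here, so a short RNA species or a library by-product might each give this excess.

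Other ways to split the sums were too few to give a share under 0.05. The real split called 826 genes at GV and the highest other 1, with 1 of 3 splits reaching the real count. At MII these were 5608 and 0 (1 of 10), between stages 7084 and 0 in controls (1 of 3) and 3711 and 27 in cKO (1 of 10), and in total RNA 9512 and 0 (1 of 3).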

How the results depend on the processing

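Alternatives chosen after seeing the data were the oocytes left out, ERCC scaling and the ERCC ratio of total RNA, sums left out of the interaction of assays, the length and GC correction of the lists, and the PAIso inserts and long tails. Of 6945 values of 518 named results, 6215 kept direction and side of the threshold, 545 lost the call (436 with 1 sum left out), 126 gained one, 4 moved and 55 reversed, all with ERCC scaling. With 2 sums per group, simulated 2-fold changes were recovered in 6% at GV in poly(A) RNA (dispersion 0.166) and in 58% in total RNA (0.0866). Both simulations changed a smaller share of genes than the data called. The cause of the changes was not tested, except that fewer genes are tested at 5 CPM, a 2-fold limit removes calls, and fewer sums enter with 1 left out.

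Without a filter GV poly(A) RNA gave 1586 genes, the stage by genotype interaction 1270 and the interaction of assays 1205. At 5 CPM they were 405 and 158 for the interactions and 6261 for total RNA, and at least 2-fold total RNA gave 5937. ERCC scaling gave 115 at GV, 15356 and 10716 between stages in control and cKO, and 6005 for the interaction. DESeq2 gave 2124 at GV and 1152 for the interaction, the fit on 2 groups 1373 at GV. With each oocyte as a sample, GV gave 3657, stage in cKO 6837 and the interaction 2391, and with limma and the f number as random block 2652, 6294 and 1256. Without the 4 oocytes the interaction gave 678 (GV 1134, MII 6080, stage 7552 in control and 4094 in cKO), and total RNA gave 8992 genes and 11 lists without cKO oocytes 1_2 and 1_3. With the length and GC trend removed camera with the preset correlation called 15 sets in total RNA. With an estimated correlation the smallest adjusted p of these camera tests was 0.075 (protein-coding genes). Leaving out 1 sum gave 135 (f2) to 239 (f3) at GV, 3358 (f6) to 5242 at MII, 4742 to 5956 between stages in control and 1471 (f4) to 3854 in cKO, 23 (f3) to 336 for the interaction, 5797 (cKO_2) to 8831 in total RNA and 3 (cKO_2) to 94 (f1) for the interaction of assays.

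Camera with an estimated correlation refers its statistic to the few residual degrees of freedom. Calls lost with it therefore cannot be put down to correlation between genes alone. It called 0 of 29 sets in each genotype comparison (1 at GV, 1 at MII and 5 in total RNA at an unadjusted p under 0.05), where the preset correlation called 4, 6 and 12 and fry 0, 5 and 15. With 1 sum left out they were 4 to 9, 4 to 6 and 10 to 14. Title numbers 1 and 2 occur in both genotypes of total RNA. As a block they gave 9330 genes and 12 lists, and a check for pairing over 2 pairs gave r = 0.193. The genotype difference (cKO minus control) in the log2 total RNA to ERCC ratio was 0.64 from summed counts and 0.67 as a median. That in PAIso tail length was 6.33 nt in pool B, 3.19 nt as a mean, and -13.25 (F3) to 7.25 (F4) with 1 F number left out, and the difference in tails over 150 nt was -0.5 (F3) to 6.5. The share of tails ending in U, that with at least 2 U, and tails per gene at 10 or 30 reads were not run.

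ERCC scaling reversed at MII Tent5c (0.09), Xrn2 (0.13), Cenpf (0.14), Eif4a2 (0.07), Psmd1 (0.07) and Psmd3 (0.08); in the interaction Lsm14b (0.3), Pcbp1 (0.42) and Smim11 (0.5); in total RNA Esr2 (0.35), mt-Nd2 (0.15), mt-Nd4 (0.23), mt-Nd1 (0.43), mt-Nd5 (0.42) and Atp5b (0.01). Between stages in controls it reversed Dis3l2 (-1.89), Cnot7 (-0.75), Pan3 (-1.77), Cnot6l (-1.95), Cnot8 (-1.67), Obox1 (-0.12), Bcl2l10 (-1.16), Mad2l1 (-1.44), Cks1b (-0.83), Lsm14a (-1.8), Lsm14b (-1.85), Arid1a (-1.79), Ezh2 (-2.15), Kmt2c (-2), Polr2c (-1.81), Cyp19a1 (-1.39), Kdr (-1.55), Pecam1 (-2.57), Postn (-0.68), Mrc1 (-2.29), Chek1 (-1.5), mt-Nd6 (-0.06), mt-Co1 (-0.34) and Psmd1 (-1.58). In cKO it reversed Dis3l2 (-1.26), Pum2 (-0.6), Cnot6l (-0.65), Cnot8 (-0.4), Fbxo43 (-0.16), Cpeb4 (-0.39), Lsm14a (-0.68), Atrx (-0.72), Kdm1a (-0.66), Ehmt1 (-0.87), Kitl (-0.36), Kdr (-0.27), Mrc1 (-1.15), Chek1 (-0.56), mt-Co1 (-0.74) and mt-Nd4 (-0.14).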

Other observations

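All values here were chosen after the data were seen. At equal depth (1000000 counts), the mean number of genes with a count was higher in cKO than in control in each of the 3 genotype comparisons. MII eggs had 13545.1 ± 307 genes in cKO and 11679.9 ± 139.8 in control (SD, n = 3 and 2), GV oocytes 15144.5 ± 407.2 and 14229 ± 341.8 in poly(A) RNA (n = 2 and 2), and 14575.2 ± 18.4 and 13302 ± 103.2 in total RNA. Genes higher in cKO at MII were also higher in GV total RNA in 1991 cases where 841.1 were expected by chance, and lower in both in 1626 (584.3). PAIso inserts had a further peak at 158 nt, with 0.2242% of reads in cKO and 0.0999% in control.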
